A study of Mus musculus with 2 samples.

How the data were processed

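Liver cells of 1 mouse per genotype label were profiled with the BD Rhapsody whole transcriptome assay and sequenced on a DNBSEQ instrument, per the labels' protocols. The deposited files hold whole-number counts per gene and barcode, not normalized, with gene symbols and no coordinates. The genome build was GRCm39, per the submitters' processing notes. The aligner, the counting tool, the collapse of molecular identifiers and the calling of cells are not given in the sources used here. Each file lists exactly 10000 barcodes. Intervals cover counting error only and take counts as independent molecules. Because collapse of identifiers is not stated, they may be too narrow even for that. The reference at hand was of an older build, so no coordinates are printed.

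Groups were taken from the genotype label of each sample. The titles go the other way, and library names go with the genotype, so values are written of the library labelled knockout or control. Barcodes were kept with at least 300 genes, 500 counts and at most 25% mitochondrial counts, which left 7917 of 10000 in the library labelled control and 8799 of 10000 in the library labelled knockout. Median counts per kept cell were 7972 and 9506. Doublets were scored per library with Scrublet in Scanpy 1.11.5. Its automatic threshold marked only 0.051% and 0.045% of cells, so it had not worked, and the fallback chosen beforehand, the top 5% of scores, was used. It removed 367 and 424 cells. Clusters mixing markers of several classes remained and were left unnamed.

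Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, without Ccn2, mitochondrial, ribosomal and haemoglobin genes, gave 30 principal components, a graph of 15 nearest neighbours and Leiden clusters at resolution 1.0. No batch correction was made, since library and genotype coincide. Clusters were named from markers fixed before the data were examined. The scoring thresholds were set after seeing the clusters: a mean marker score of at least 1, at least 3 markers detected in at least 10% of cells, a level of at least 0.1 of the highest for the class or for another of its lineage, no class of another lineage at 0.2 or more of its highest level, and no more genes of another class than of its own among the 10 leading genes. These rules kept 2117 cells (28.0%) of the library labelled control and 1502 (17.9%) of the library labelled knockout out of the classes. Cluster 4 scored highest for lymphatic markers, at a level of 0.011, and was named endothelial through its sinusoidal level of 0.588. All endothelial clusters formed 1 class, and stellate and smooth muscle clusters were kept apart as planned. A pool of stellate and smooth muscle clusters and the use of cluster 0 alone were added after the clusters had been seen, as was a Kupffer count with unnamed clusters. An interim version had used that pool as the stellate class and had picked lists for emphasis by their values. The planned separation and all lists of each class were then restored.

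Counts were summed over the cells of a class in each library and expressed as CPM of the class total, with exact Poisson intervals for levels and exact conditional intervals for ratios. Shares have exact Clopper-Pearson intervals at 95%. A count of 0 was set to a floor of 3 counts for a ratio. Gene lists were fixed before the data were examined, and a member counted as measured with at least 20 counts over both libraries and 10 CPM in at least 1. A list's median log2 ratio has an interval from resampled Poisson counts and a percentile among 10000 random lists of the same size matched on mean expression, which describes these libraries and is no test. Members at least 1.5-fold apart were counted as higher or lower by size alone.

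Named genes followed a rule fixed beforehand. It took Ccn2 in every class, and per list up to 4 members with the largest log2 ratio of at least 1.5-fold, or else the 2 of highest CPM. In endothelial, stellate and Kupffer cells it also took the 10 highest and 10 lowest ratios among genes with at least 50 CPM in 1 library and 100 counts in all. That last part left out mitochondrial, ribosomal, haemoglobin, immunoglobulin, Gm and Rik genes, the hepatocyte list, and genes below 0.5 times the highest CPM of another named class, as a guard against free RNA. Only some of the genes the rule took are printed, as examples picked after their values were known.

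The ratio and list code was tested on simulated Poisson counts with 200 genes changed by known folds. This checks the code, not whether the real counts vary that way. In the endothelial simulation of 8636 genes, 95.4% of intervals covered the simulated ratio, and all 50 genes raised by a fold of 2 passed the size rule. In the stellate simulation of 9092 genes, 48 of 50 such genes passed, and 4.86% of unchanged genes passed it by chance. In the Kupffer simulation of 8433 genes, 95.2% of intervals covered the simulated ratio.

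The alternatives were stricter and looser cell filters, doublets kept, Leiden resolutions 0.5 and 2.0, clustering per library, TMM factors from edgeR 4.0.16, size factors from DESeq2 1.42.0, totals without mitochondrial, haemoglobin and hepatocyte genes, means of per-cell CPM, thinned cells, and other minimum CPM. Cells that only the looser filter admitted had no doublet score. Analyses used Python 3.11.15, SciPy 1.17.1 and R 4.3.3.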

Results

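The data came from single-cell RNA sequencing of liver cells from mice that had undergone partial ligation of the inferior vena cava, a model of hepatic congestion in which outflow of blood from the liver is impeded. By the labels, 1 library came from a male mouse with an endothelial-specific deletion of Ctgf (current symbol Ccn2), which encodes the matricellular protein connective tissue growth factor, and the other from a littermate control. The genotype given for the knockout has a tamoxifen-inducible Cre recombinase under the Cdh5 promoter, which is active in endothelial cells, together with floxed Ctgf alleles. The genotype given for the control has the floxed alleles alone. Most hepatocytes, dead cells and erythrocytes had been removed from the suspensions before capture, so the shares of cells below describe the suspension and not the liver. The titles of the samples contradicted their genotype labels: the sample with the Cre genotype was titled as the control, and the sample without Cre as the knockout. Groups followed the genotype labels, with which the library names went, and each direction below is that of the library labelled knockout against the library labelled control.

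With 1 library per label, no test was possible, no difference has a replicate check, and differences between the animals, the surgery and the genotype were not separable. Intervals are 95% intervals that cover counting error only. Each library held 10000 barcodes, with 106208933 counts in the library labelled control and 129802501 in the library labelled knockout. After filtering and removal of called doublets, 7550 and 8375 cells remained.

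Ccn2 was the first gene examined, since it checks the labels. In endothelial cells its level was 1088 CPM (1070 to 1106) in the library labelled control and 5.0 CPM (4.20 to 5.90) in the library labelled knockout, from 13580 and 139 counts in 1691 and 3395 cells. The log2 ratio was -7.77 (-8.02 to -7.52), a level 218-fold lower. A Ccn2 count was found in 73.9% of endothelial cells (71.8 to 76.0, exact binomial) of the library labelled control and in 2.50% (2.00 to 3.09) of the library labelled knockout. With each cell thinned to 4047 counts these shares were 68.2% and 1.77%, after 113 and 395 shallower cells were left out. In B cells, which should lack the gene, the shares were 8.89% and 0.79%, at median depths of 4689 and 4084 counts against 6472 and 7124 in endothelial cells. The result went with the genotype labels and against the titles. The labels do not say which part of the gene the deletion removes.

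Outside the endothelium, Ccn2 stayed abundant in mesenchymal classes of both libraries. Stellate cells, the retinoid-storing pericytes of the liver, had 714 CPM (670 to 760) in the library labelled control and 1041 CPM (1014 to 1069) in the library labelled knockout, a log2 ratio of 0.54 (0.45 to 0.64). Pooling in cluster 7, described with the stellate cells, turned this ratio to -0.22. The stellate ratio was also negative with the stricter and the looser cell filter, with called doublets kept and at the lower clustering resolution. It stayed positive but was smaller at the higher resolution and with each library clustered on its own. With thinned cells and with means of per-cell CPM it was larger. The direction in stellate cells thus depended on the processing. Mesothelial cells had 752 and 650 CPM, a log2 ratio of -0.21 (-0.32 to -0.10). Levels were low in Kupffer cells, the resident macrophages of the liver, at 17.1 and 3.21 CPM. Cdh5, whose promoter drives the Cre, stood at 482 and 643 CPM there, so Cre activity in Kupffer cells was not excluded. Ccn2 was also low in T cells at 26.1 and 3.69 CPM and in B cells at 19.3 and 1.57 CPM. Conventional dendritic cells had 55.5 and 5.83 CPM. Erythroid cells, only 50 and 43, had 376 and 3.33 CPM, and plasma cells, only 31 and 34, had 86.5 and 0 CPM. NK or ILC1 cells had 231 CPM (205 to 260) in the library labelled control and 0 counts in the library labelled knockout. Against a floor of 3 counts this was 48.2-fold lower, and the counting interval put it at 38.9-fold or more.

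**Figure D1:**
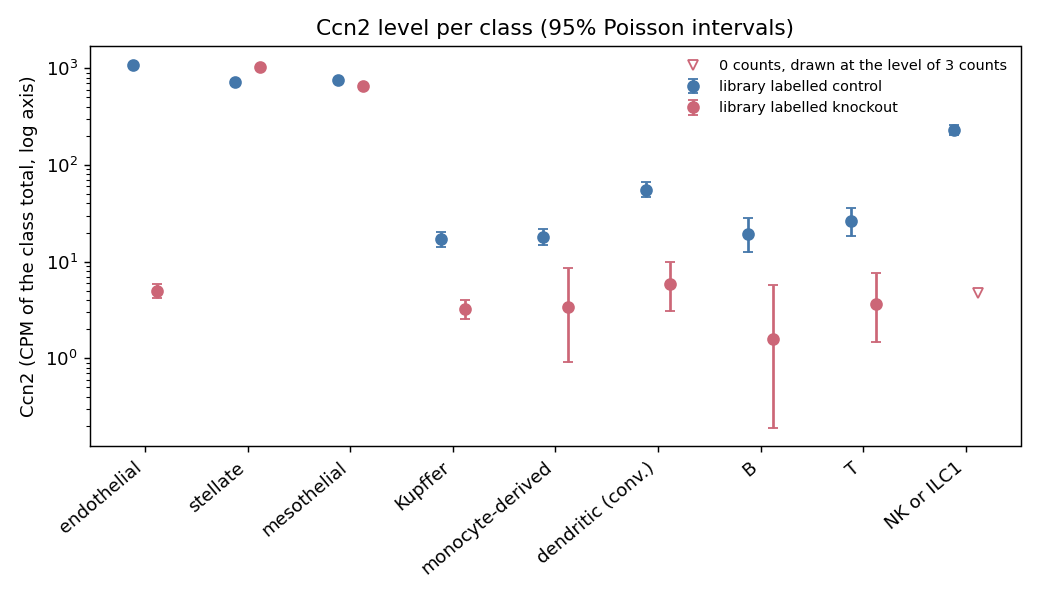
Ccn2 level per cell class, in CPM of the class total on a log axis, for the library labelled control (blue) and the library labelled knockout (red). Points are sums over cells of 1 library, bars are 95% Poisson intervals covering counting error only, and the open triangle marks 0 counts; endothelial cells stand at 1088 and 5.0 CPM, while stellate cells stand at 714 and 1041 CPM.

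The composition of the suspensions differed in several classes. Endothelial cells made up 22.4% (21.5 to 23.4) of kept cells in the library labelled control and 40.5% (39.5 to 41.6) in the library labelled knockout. Kupffer cells made up 8.72% (8.09 to 9.37) and 16.6% (15.8 to 17.4). Counted with the unnamed clusters 8, 13 and 16, which scored highest for Kupffer markers, they made up 27.2% and 24.7%, the other direction. This count was added after the shares had been seen. Clusters 8 and 13 also held sinusoidal markers. Cluster 13 had a median of 23778.5 counts against 15385 in Kupffer cluster 1, so doublets there were not excluded. Cluster 22, at 1.89% and 4.54%, was not counted in. It scored highest for stellate markers but held Kupffer markers at 0.54 of their highest level. Monocytes and monocyte-derived macrophages made up 12.6% (11.9 to 13.4) and 1.71% (1.44 to 2.01). Neutrophils made up 0.48% (0.33 to 0.66) and 2.61% (2.28 to 2.98), from 36 and 219 cells. NK or ILC1 cells made up 2.28% and 1.16%, T cells 3.26% and 3.93%, and B cells 2.98% and 3.02%, with overlapping intervals for T cells and for B cells. Hepatocytes made up 3.52% and 1.0%. Stellate cells made up 2.23% and 6.27%, while pooled with cluster 7 they made up 8.90% and 6.53%, the other direction. Conventional dendritic cells made up 3.47% and 2.16%, a direction that turned at the lower clustering resolution. Of non-parenchymal cells, the endothelial shares were 23.2% and 40.9% and the Kupffer shares 9.03% and 16.7%. Clusters left unnamed held 28% and 17.9% of cells, and 20.8% and 11.8% of barcodes had been set aside for mitochondrial counts. The files held no barcode below 3311 and 2848 counts in turn, so cells with little RNA may be missing to unlike degrees. Each of these points bears on every share. The Kupffer difference was smaller under several clusterings: its log2 ratio of shares was 0.93 as reported and 0.31 with called doublets kept. With each library clustered on its own, the T cell share had a log2 ratio of -0.64, against 0.27 as reported.

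**Figure D2:**
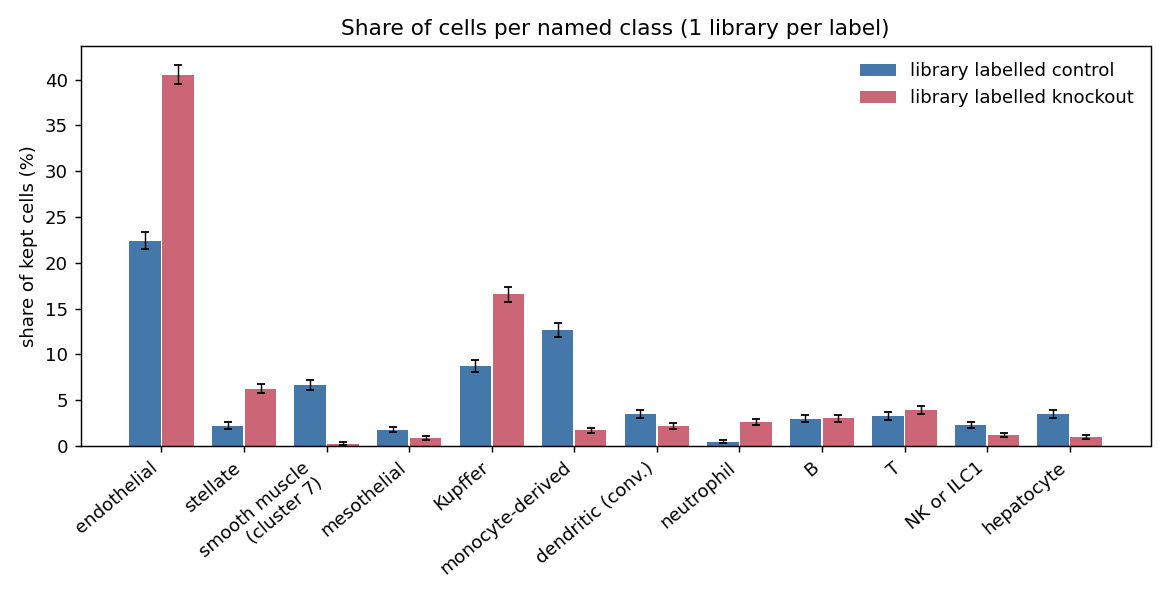
Share of kept cells (percent) in each named class for the library labelled control (blue) and the library labelled knockout (red), 1 library each. Bars start at 0 and error bars are exact 95% binomial intervals covering counting error only; endothelial cells stand at 22.4% and 40.5%, and monocyte-derived cells at 12.6% and 1.71%.

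In endothelial cells, more genes of the sinusoidal type were higher than lower in the library labelled knockout, and more genes of capillary-type endothelium were lower than higher. Of 16 measured genes of sinusoidal identity and scavenging, 8 were at least 1.5-fold higher and 2 lower, with a median log2 ratio of 0.48 (0.45 to 0.52), at percentile 99.99 of matched random lists. Dnase1l3, an extracellular nuclease, stood at 2362 and 5821 CPM, and Bmp2, which regulates hepatocyte hepcidin, at 736 and 1761 CPM. Lyve1, a hyaluronan receptor of the same list, was lower at 4585 and 1360 CPM. Of 14 capillarization genes, 7 were lower and 2 higher, with a median of -0.65 (-0.66 to -0.63), below all 10000 random lists. Plvap, the diaphragm protein of fenestrae and caveolae, stood at 1177 and 299 CPM, and Apln, a peptide of angiogenic endothelium, at 129 and 13.8 CPM.

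Angiocrine factors had a median of -0.62, with 7 of 14 lower and 3 higher, including Inhbb at 341 and 96.3 CPM and Wnt2 at 42.5 and 121 CPM. Coagulation and fibrinolysis genes had a median of -0.89, with 5 of 9 lower, including Vwf at 63.2 and 21.1 CPM. Leukocyte adhesion genes and chemokines had a median of -0.66, with 5 of 9 lower, including Ccl2 at 34.9 and 7.62 CPM and Selp at 106 and 36.5 CPM. Targets of YAP and TEAD, the transcription factors that drive Ccn2 itself, had a median of -0.33 without Ccn2, with 7 of 16 lower and 0 higher. Igfbp3 stood at 39.7 and 6.62 CPM. The CCN family, with 3 members measured and Ccn2 among them, had a median of -0.84, the value of Ccn1, the closest relative of Ccn2, at 90.7 and 50.8 CPM. The median was -0.21 for TGF-beta and BMP response, -0.26 for vasoactive genes, -0.41 for pericentral genes and 0.09 for periportal genes. Members of these lists went both ways: Smad7 stood at 195 and 434 CPM, Edn1 at 185 and 86.4 CPM, and Wnt9b at 61.6 and 17.3 CPM beside Cdh13 at 59.5 and 177 CPM.

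Among single genes chosen by size, the lowest log2 ratios after Ccn2 were those of Steap2, a metalloreductase, at -5.81 (56.6 and 1.01 CPM), Fmo2 at -3.50, Xylt1 at -3.37 and Fbln2 at -3.23. The highest were those of Cyp26b1, which degrades retinoic acid, at 3.16 (42.1 and 376 CPM), Car8 at 2.55, Col13a1 at 2.51, Tpbgl at 2.41 and Hlf at 2.16. Fmo2 and Fbln2 were among the 10 leading genes of cluster 4, with 497 and 123 cells. Cyp26b1, Car8, Col13a1 and Tpbgl were among those of cluster 24, with 13 and 1310 cells. These ratios thus partly restate which library filled which cluster, though Tpbgl had one of 1.42 within cluster 0.

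These endothelial values compared different clusters. The clusters were drawn from variable genes of both libraries, and of these lists only Ccn2 was left out. Cells of cluster 0 were therefore alike by selection, so medians within it cannot tell a changed mix of cells from a change within cells. Clusters 0 and 4 held 85.8% of the endothelial cells of the library labelled control and 12.3% of those of the library labelled knockout, and clusters 19 and 24 held 5.50% and 79.1%. Within cluster 0, with 954 and 293 cells, Ccn2 had a log2 ratio of -7.61, while the medians were -0.063 for capillarization, 0.011 for angiocrine factors, -0.07 for coagulation, 0.045 for leukocyte adhesion and 0.28 for sinusoidal identity. Ccn1 turned to 0.44 within cluster 0. In cluster 28, of vascular type, Ccn1 had a log2 ratio of 2.38 and Vwf one of 0.94. Other genes kept their direction in clusters 0 and 28: Inhbb at -1.41 and -2.74, Plvap at -1.83 and -0.98 and Lyve1 at -0.88 and -2.08. The pericentral median turned to 0.15 within cluster 0, the vasoactive to 0.073 and the periportal to -0.12, and that of TGF-beta and BMP response turned to 0.026 with at least 50 CPM required. TMM and median-of-ratios scaling moved endothelial log2 ratios up by 0.12 and 0.14.

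In stellate cells, more matrix genes were lower than higher in the library labelled knockout. Neither the contractile nor the quiescence list stood apart in the class as bounded here. Of 24 collagen and matrix genes, 10 were at least 1.5-fold lower and 3 higher, with a median of -0.51 (-0.56 to -0.43), below all 10000 random lists. Thbs2 stood at 188 and 52.8 CPM, and Thbs1 went the other way at 38.5 and 163 CPM. The median was -0.44 for matrix remodelling enzymes, -0.24 for collagen processing and cross-linking, where Plod2 stood at 159 and 64.0 CPM, and -0.27 for receptors reported for CCN2. The contractile median was 0.15 (0.03 to 0.25), with Acta2, the smooth muscle actin of activated stellate cells, at 195 and 82.7 CPM and Myh11 at 71.3 and 126 CPM. The quiescence list had a median whose interval ran from -0.03 to 0.14, with 1 of 18 members higher and 1 lower. YAP and TEAD targets had a median of 0.05, TGF-beta and BMP response -0.12, and mesenchymal cytokines and chemokines 0.17. Ccn1 was the highest of the single genes chosen by size, at 111 and 1265 CPM, a log2 ratio of 3.51 (3.28 to 3.75). Others among the 10 highest were Clstn2 at 3.02, Kcnk3 at 2.22, Notch3 at 1.86 and Heyl, a Notch target, at 1.75. The 10 lowest included Zbtb8b at -2.44, Mid1 at -2.43, Gpx3 at -2.43 and Adm at -1.72.

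The stellate values depended on where the class was bounded. The class held 168 and 525 cells, all in cluster 17. Cluster 7, with 504 and 22 cells, scored highest for smooth muscle markers and was kept apart as planned, with nearly all of its cells from 1 library. Other filters, other resolutions and separate clustering each drew cells of cluster 7 into the stellate class. Under each of them the contractile median was negative and the quiescence median positive. Myh11, a member of the contractile list, was also a smooth muscle marker used in naming, so the naming bears on that list. Pooling the clusters was added after they had been seen. Pooled, the medians were -0.97 for collagens and matrix, -1.15 for contractile genes, 0.87 for quiescence, 0.13 for receptors reported for CCN2 and -0.29 for YAP and TEAD targets. The cytokine median turned to -0.24 at the higher clustering resolution.

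**Figure D3:**
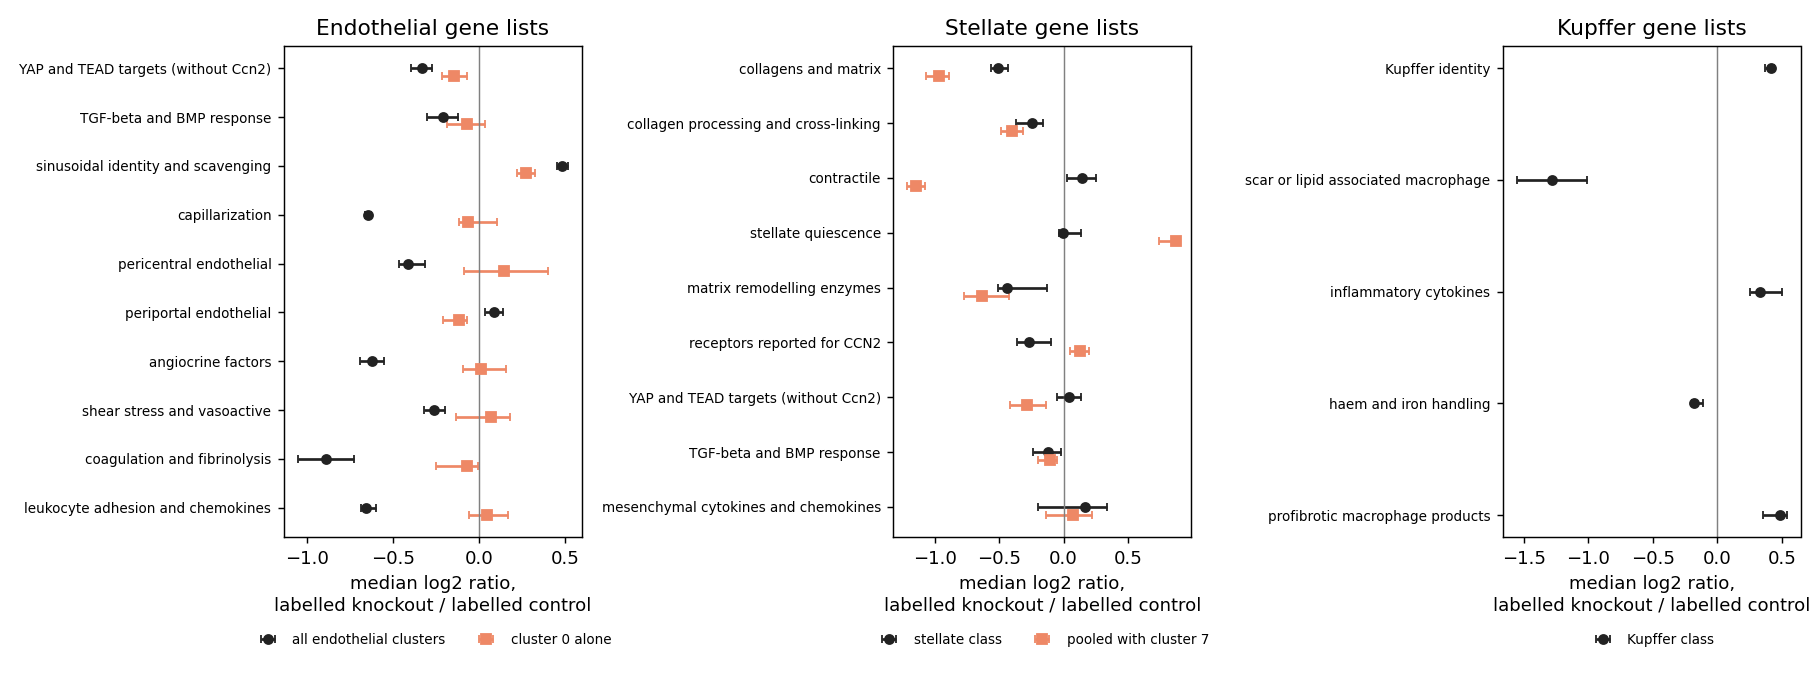
Median log2 ratio (library labelled knockout over library labelled control) of gene lists fixed beforehand, in endothelial, stellate and Kupffer cells. Bars are 95% intervals from counting error only; black circles are the classes as reported and orange squares cluster 0 alone (left) or stellate cells pooled with cluster 7 (middle), where capillarization stands at -0.65 and -0.063 and contractile genes at 0.15 and -1.15.

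In Kupffer cells, most measured genes of scar- or lipid-associated macrophages were lower in the library labelled knockout, while most identity genes differed by less than 1.5-fold. Of 12 scar-associated genes, 8 were at least 1.5-fold lower and 0 higher, with a median of -1.28 (-1.56 to -1.01), below all 10000 random lists. This median ran from -2.22 at the higher clustering resolution to -0.61 with at least 50 CPM required. Trem2, a lipid-sensing receptor, stood at 201 and 44.0 CPM, Cd9 at 64.6 and 9.10 CPM and Gpnmb at 13 and 0.65 CPM. The unnamed macrophages of cluster 16, at 7.32% and 0.90% of cells, had Trem2 at 424 and 98.0 CPM and Gpnmb at 321 and 60.3 CPM, and RNA or cells of that kind within the Kupffer class were not separated. Of 13 identity genes, 3 were at least 1.5-fold higher and 1 lower, with a median of 0.41 (0.37 to 0.44). Folr2 stood at 797 and 1277 CPM, and Marco, a scavenger receptor, was lower at 802 and 357 CPM. Inflammatory cytokines had a median of 0.33, with Il1b at 30.4 and 144 CPM and Il18 at 203 and 95.1 CPM. With each library clustered on its own this median was -0.013. Haem and iron genes had a median of -0.18, with Hmox1 at 1703 and 1110 CPM, a direction that turned under 3 alternatives. Profibrotic products had a median of 0.49, a direction that turned under 5. The list included Mmp9, also a neutrophil marker, at 1.39 and 51.3 CPM. MHC class II genes had a median of 0.67, with Cd74 at 1351 and 2391 CPM. Cxcl13 was among the highest single genes at 200 and 895 CPM.

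Monocyte-derived cells were few in the library labelled knockout, 143 against 954. Their haem and iron list had a median of -0.62 (-0.81 to -0.47), with Hmox1 at 244 and 94.8 CPM, and Kupffer identity genes one of -0.78 (-0.98 to -0.31), which turned to 0.15 at the lower clustering resolution and to 0.061 with called doublets kept. The medians were -0.23 for scar-associated genes, -0.22 for inflammatory cytokines and -0.05 for profibrotic products, each with an interval that included 0. MHC class II genes had a median of -0.32 and hypoxia genes one of 0.28.

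In T cells, cytotoxicity genes had a median of 0.55 (0.25 to 0.80), with 6 of 12 higher, including Ccl5 at 1622 and 3163 CPM. Naive and central memory genes had a median of 0.58 (0.45 to 0.64), and activation and exhaustion genes one of -0.62 (-0.80 to -0.26), with Tnfrsf9 at 78.3 and 14.8 CPM and Pdcd1 at 28.8 and 11.1 CPM. MHC class II transcripts, typical of antigen-presenting cells, had a median of -1.12 in T cells and -1.22 in NK or ILC1 cells. Of 16 cell cycle genes in T cells, 15 were lower, with a median of -0.81. In NK or ILC1 cells, 15 of 16 cell cycle genes were lower, with a median of -1.33, and the medians were 0.27 for cytotoxicity, 0.04 for activation and exhaustion and 0.56 for naive and memory genes. Gzma, a granzyme, stood at 3373 and 1654 CPM and Prf1, which encodes perforin, at 127 and 237 CPM. B cells and conventional dendritic cells had MHC class II medians of 0.16 and -0.22. Cell cycle genes had a median of 0.69 in conventional dendritic cells, with 8 of 16 higher, including Mki67 at 133 and 340 CPM. That class joined cluster 9, with 178 and 87 cells, and cluster 11, with 84 and 94 cells. The mix of clusters thus differed between the libraries, and medians within each cluster were not computed. In B cells the cell cycle interval ran from -0.28 to 0.55. None of the medians of T, NK or ILC1, B and conventional dendritic cells was recomputed under another filter, clustering or scaling.

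Several lists moved with the library in every class compared, with RNA from other cells among them. Over the 8 classes, the interferon response list had medians from -1.22 to -0.58 and hepatocyte transcripts, a measure of RNA from outside the cell, medians from -1.86 to -0.62. Mup3, of the same list, went the other way, with a log2 ratio of 2.10 in Kupffer cells and 1.83 in T cells. Cxcl10, of the interferon list, was higher in Kupffer cells, at 1.88, and in B cells, at 1.35. It was lower in stellate cells, at -1.47, and in conventional dendritic cells, at -1.02. Immediate early genes had medians from 0.17 to 1.03, but in 7 smaller classes the median lay above 0 beyond counting error in 2 and below 0 in 2. In endothelial cells, stellate cells and Kupffer cells in turn, the interferon medians were -0.63, -0.70 and -0.60, the hepatocyte medians -1.42, -0.62 and -0.67, and the immediate early medians 0.53, 0.83 and 1.03. Hypoxia genes had medians of -0.30, -0.68 and -0.38, and cell cycle genes -0.63, -0.77 and -1.12. The endothelial cell cycle median was 0.075 within cluster 0. The stellate one was 0.0061 without mitochondrial, haemoglobin and hepatocyte genes in the totals. Mitochondrial genes had medians of 0.05, 0.24 and -0.23, and the endothelial and stellate ones turned under several alternatives. The MHC class II median was -1.23 in endothelial cells and -1.74 in stellate cells, and the erythroid median -2.04, -3.68 and -0.06. The Kupffer erythroid median turned with called doublets kept and with thinned cells.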

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

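The tests of explanations given further below were chosen after the patterns they address had been seen. Only the immediate early test had its bounds set before its values were seen. None of the differences between classes was tested, since each label has 1 library.

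Some lists went opposite ways in different cell classes. The MHC class II list had a median log2 ratio of -1.74 in stellate cells and 0.67 in Kupffer cells. The cell cycle list had one of -1.33 in NK or ILC1 cells and 0.69 in conventional dendritic cells. The mix of clusters 9 and 11 within the dendritic class differed between the libraries. Erythroid transcripts had a median log2 ratio of -3.68 in stellate cells and of 3.71 in conventional dendritic cells. The middle member in dendritic cells, Alas2, had 0 counts in the library labelled control, set to the floor of 3 counts. Its log2 ratio of 3.71 had a lower counting limit of 3.34.

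Among the clusters outside every comparison, clusters 22 and 29 held a larger share of cells in the library labelled knockout, while all others held a larger share in the library labelled control. Cluster 22, with stellate and Kupffer markers together, held 4.54% of its cells against 1.89% in the library labelled control. Its cells had a median of 29791 counts, against 8158 in stellate cluster 17 and 15385 in Kupffer cluster 1, and remaining doublets were not excluded. Cluster 29, led by Mpo, Ctsg and Elane, genes of granulocyte precursors, held 2.32% against 1.31%.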

How the results depend on the processing

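No paired analysis was possible because each label has 1 library and no test was run. Over 75 results and 904 alternative values, 564 stayed within the counting interval of the reported value, 285 left it and 55 changed sign where the reported interval had excluded 0. Of the 890 alternative log2 values, 800 kept the direction. List medians were recomputed only in endothelial, stellate, Kupffer and monocyte-derived cells. Those of T, NK or ILC1, B and conventional dendritic cells have no alternative value. The endothelial Ccn2 ratio kept its direction in each alternative. Each other clustering placed cells of cluster 7 in the stellate class, from 157 of 839 at the higher resolution to 506 of 1199 at the lower one. The use of cluster 0 alone, the stellate pool and the Kupffer count with unnamed clusters were added after seeing the data. With the unnamed clusters that scored highest for Kupffer cells counted in, the Kupffer share had a log2 ratio of -0.13.

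With the stricter cell filter, the Ccn2 log2 ratio was -0.16 in stellate cells. Share log2 ratios were 0.64 for endothelial cells, -0.35 for stellate cells, 0.53 for Kupffer cells and 0.57 for T cells. Endothelial medians were -0.48 for TGF-beta response, 0.63 for sinusoidal identity, -0.44 for capillarization, -0.53 for pericentral genes, 0.22 for periportal genes, -0.73 for leukocyte adhesion and -0.016 for mitochondrial genome. Stellate medians were -0.90 for collagens and matrix, -1.15 for contractile, 0.74 for stellate quiescence, 0.074 for CCN2 receptors, -0.40 for YAP and TEAD targets, -0.20 for mesenchymal cytokines and -0.13 for mitochondrial genome. Kupffer medians were 0.52 for Kupffer identity, -2.06 for scar-associated genes, 0.18 for haem and iron handling and -0.018 for profibrotic products. Monocyte-derived medians were -1.04 for Kupffer identity, 0.40 for scar-associated genes, -0.47 for haem and iron handling and 0.0017 for mitochondrial genome. With the looser cell filter, the Ccn2 log2 ratio was -0.21 in stellate cells. Share log2 ratios were -0.38 for stellate cells and -0.40 for B cells. Endothelial medians were -0.076 for TGF-beta response and -0.043 for mitochondrial genome. Stellate medians were -0.89 for collagens and matrix, -0.40 for collagen processing, -1.09 for contractile, 0.83 for stellate quiescence, -0.68 for remodelling enzymes, 0.13 for CCN2 receptors, -0.29 for YAP and TEAD targets and -0.13 for mitochondrial genome. Monocyte-derived medians were -0.46 for haem and iron handling. With called doublets kept, the Ccn2 log2 ratio was -0.32 in stellate cells. Share log2 ratios were -0.35 for stellate cells and 0.31 for Kupffer cells. Stellate medians were -0.97 for collagens and matrix, -0.42 for collagen processing, -1.14 for contractile, 0.77 for stellate quiescence, -0.64 for remodelling enzymes, -0.051 for CCN2 receptors, -0.26 for YAP and TEAD targets and -0.055 for mitochondrial genome. Kupffer medians were 0.50 for Kupffer identity, -1.87 for scar-associated genes, 0.21 for inflammatory cytokines, 0.14 for haem and iron handling, -0.028 for profibrotic products and 0.29 for erythroid transcripts. Monocyte-derived medians were 0.061 for Kupffer identity. At Leiden resolution 0.5, the Ccn2 log2 ratio was -0.24 in stellate cells. Share log2 ratios were -0.41 for stellate cells, -0.34 for B cells and 0.013 for dendritic cells. Endothelial medians were -0.086 for TGF-beta response and -0.71 for coagulation. Stellate medians were -1.07 for collagens and matrix, -0.44 for collagen processing, -1.19 for contractile, 0.83 for stellate quiescence, -0.71 for remodelling enzymes, 0.10 for CCN2 receptors, -0.26 for YAP and TEAD targets and -0.073 for mitochondrial genome. Monocyte-derived medians were 0.15 for Kupffer identity, 0.24 for scar-associated genes, -0.48 for inflammatory cytokines and -0.37 for haem and iron handling. At Leiden resolution 2.0, the Ccn2 log2 ratio was 0.25 in stellate cells. Share log2 ratios were 0.56 for stellate cells and 0.40 for Kupffer cells. Endothelial medians were -0.27 for YAP and TEAD targets, -0.089 for TGF-beta response, 0.13 for periportal genes and -0.60 for leukocyte adhesion. Stellate medians were -0.21 for collagens and matrix, -0.38 for contractile, 0.58 for stellate quiescence, 0.054 for CCN2 receptors, -0.13 for YAP and TEAD targets, -0.33 for TGF-beta response and -0.24 for mesenchymal cytokines. Kupffer medians were 0.58 for Kupffer identity, -2.22 for scar-associated genes, 0.066 for inflammatory cytokines, 0.088 for haem and iron handling and -0.0024 for profibrotic products. With each library clustered on its own, the Ccn2 log2 ratio was 0.039 in stellate cells. Endothelial cells with a Ccn2 count made up 71.4% in the library labelled control. Share log2 ratios were 1.26 for endothelial cells, 0.34 for stellate cells, 0.36 for Kupffer cells and -0.64 for T cells. Endothelial medians were -0.46 for YAP and TEAD targets, -0.50 for TGF-beta response, 0.56 for sinusoidal identity, -0.68 for capillarization, -0.78 for pericentral genes, 0.0037 for periportal genes and -0.37 for vasoactive genes. Stellate medians were -0.75 for collagens and matrix, -0.43 for collagen processing, -0.55 for contractile, 0.26 for stellate quiescence, -0.66 for remodelling enzymes, -0.29 for TGF-beta response, 0.38 for mesenchymal cytokines and -0.0024 for mitochondrial genome. Kupffer medians were 0.64 for Kupffer identity, -2.17 for scar-associated genes, -0.013 for inflammatory cytokines, -0.082 for haem and iron handling and 0.11 for profibrotic products. Under TMM scaling, endothelial medians were -0.21 for YAP and TEAD targets, -0.090 for TGF-beta response, 0.61 for sinusoidal identity, -0.52 for capillarization, -0.29 for pericentral genes, 0.21 for periportal genes, -0.50 for angiocrine factors, -0.14 for vasoactive genes and -0.54 for leukocyte adhesion. Kupffer medians were 0.45 for Kupffer identity. Under median-of-ratios scaling, endothelial medians were -0.19 for YAP and TEAD targets, -0.067 for TGF-beta response, 0.63 for sinusoidal identity, -0.50 for capillarization, -0.27 for pericentral genes, 0.23 for periportal genes, -0.48 for angiocrine factors, -0.12 for vasoactive genes and -0.51 for leukocyte adhesion. Stellate medians were -0.43 for collagens and matrix. Kupffer medians were 0.46 for Kupffer identity. With cells thinned to one depth, the Ccn2 log2 ratio was -7.47 in endothelial cells and 0.77 in stellate cells. Endothelial cells with a Ccn2 count made up 68.2% in the library labelled control and 1.77% in the library labelled knockout. Endothelial medians were -0.32 for vasoactive genes. Stellate medians were -0.15 for collagen processing, 0.28 for contractile and 0.16 for stellate quiescence. Kupffer medians were 0.15 for erythroid transcripts. Monocyte-derived medians were -0.24 for Kupffer identity, 0.021 for inflammatory cytokines and -0.37 for haem and iron handling. With the mean of per-cell CPM, the Ccn2 log2 ratio was 0.82 in stellate cells. Endothelial medians were 0.020 for periportal genes and -0.73 for leukocyte adhesion. Stellate medians were 0.35 for contractile. With no minimum CPM, endothelial medians were -0.66 for YAP and TEAD targets, -0.34 for TGF-beta response and -0.72 for leukocyte adhesion. Kupffer medians were 0.22 for inflammatory cytokines and -0.077 for profibrotic products. Monocyte-derived medians were 0.19 for inflammatory cytokines. With at least 50 CPM required, endothelial medians were -0.14 for YAP and TEAD targets, 0.026 for TGF-beta response, -0.80 for capillarization, 0.18 for periportal genes, -0.50 for angiocrine factors, -0.49 for coagulation and -0.29 for leukocyte adhesion. Stellate medians were -0.24 for mesenchymal cytokines. Kupffer medians were -0.61 for scar-associated genes and -0.023 for profibrotic products. Monocyte-derived medians were -1.01 for Kupffer identity. With mitochondrial, haemoglobin and hepatocyte genes left out of the totals, stellate medians were 0.0061 for cell cycle. Kupffer medians were -0.20 for haem and iron handling. Within cluster 0 alone, endothelial medians were -0.15 for YAP and TEAD targets, -0.070 for TGF-beta response, 0.28 for sinusoidal identity, -0.063 for capillarization, 0.15 for pericentral genes, -0.12 for periportal genes, 0.011 for angiocrine factors, 0.073 for vasoactive genes, -0.070 for coagulation, 0.045 for leukocyte adhesion, 0.075 for cell cycle and -0.024 for mitochondrial genome. With the stellate and smooth muscle clusters pooled, the Ccn2 log2 ratio was -0.22 in stellate cells. Stellate medians were -0.97 for collagens and matrix, -0.40 for collagen processing, -1.15 for contractile, 0.87 for stellate quiescence, -0.64 for remodelling enzymes, 0.13 for CCN2 receptors, -0.29 for YAP and TEAD targets and -0.079 for mitochondrial genome.

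Some classes had no value: B cells, hepatocytes and monocyte-derived cells with each library clustered on its own, B cells with the stricter filter and T cells at resolution 0.5. The cause of each move was not tested. Intervals come from counts alone, so depth limits them and spread between animals is unknown.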

Other observations

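The tests of Ccn2 in lymphocytes and of Steap2 were chosen only after the results had been seen, while the bounds of the immediate early test were set before its values were seen. Genotype itself stays untested as an explanation, because each label has 1 library.

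Macrophages of cluster 16, led by Mmp12, Gpnmb and Trem2, and left unnamed, made up 7.32% (6.75 to 7.94) of cells in the library labelled control and 0.90% (0.71 to 1.12) in the library labelled knockout. Cycling cells of cluster 8 made up 4.40% and 0.91%. Of the endothelial cells of the library labelled knockout with a Ccn2 count, 70 of 85 had 1 count, and 5 of 3395 endothelial cells had 5 counts or more, with a highest value of 17. In the library labelled control 785 of 1691 had 5 or more.

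Ccn2 was also lower in lymphocytes of the library labelled knockout, which the Cre driver does not target. A candidate explanation is endothelial RNA in those droplets, free or from doublets. In the library labelled control, the level of 10 sinusoidal markers, as a share of their endothelial level, predicts 24.5 CPM of Ccn2 in B cells, 22.5 in T cells and 178 in NK or ILC1 cells, against 19.3, 26.1 and 231 CPM observed. The observed over predicted ratios were 0.79 (0.51 to 1.16), 1.16 (0.82 to 1.59) and 1.30 (1.15 to 1.46), and 1.22 (1.10 to 1.36) for the pool, which is consistent with that explanation. These intervals cover counting of Ccn2 alone and take the predicted level as exact. In the pool, single markers ranged from 5.81% to 8.999% of their endothelial level, around the 6.55% used. Of 172 NK or ILC1 cells, 27 had a Ccn2 count, 14 had 5 or more and the highest had 72. By contrast, 17 of 20 positive B cells and 17 of 19 positive T cells had 1 count. The NK or ILC1 interval lies above 1 but may be too narrow. Doublets and a further source there both stay open.

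The list of immediate early and heat shock genes had a median above 0 in 8 of 8 classes, lymphocytes included, from 0.17 to 1.03, though not each member was higher: Hspa8 had a log2 ratio of -0.32 in B cells and -0.28 in T cells. A difference in handling or dissociation that reached all cells of a library was tested in 7 smaller classes outside these 8. The median lay above 0 beyond counting error in 2 of 7 and below 0 in 2, mesothelial cells at -0.14 and neutrophils at -0.19. That decides neither way, so handling, surgery and genotype stay open. Ccn1, itself an immediate early gene, had a log2 ratio of 3.51 in stellate cells and -0.84 in endothelial cells, though 0.44 within cluster 0 and 2.38 within cluster 28.

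Among the single genes chosen by size, Steap2 had the lowest endothelial log2 ratio after Ccn2, at -5.81. A variant or mapping difference carried by all cells of the mouse would lower it elsewhere, but in mesothelial cells the ratio was -0.020 (-0.40 to 0.35), at 58.5 and 57.7 CPM, which argues against it. A different mix of endothelial clusters as the whole cause is argued against by a ratio of -3.72 (-4.73 to -2.86) within cluster 0. A different mix of cells inside cluster 0 was not tested. In cluster 28 the ratio was -0.10 (-3.68 to 3.03), from 3 and 2 counts, which decides nothing. Steap2 was lower in stellate cells too, at -0.94 (-1.66 to -0.19), and in these pooled with cluster 7 at -1.23 (-1.66 to -0.82). Sinusoidal markers stood at 0.070 of their highest level in cluster 17 and at 0.11 in cluster 7. Endothelial RNA was therefore not excluded as a source of these stellate values, and a cause beyond endothelial cells stays open. In hepatocytes the ratio was -0.34 (-0.99 to 0.31). In Kupffer cells it was -3.10, from 11 and 4 counts, at 1.39 and 0.16 CPM. Sinusoidal markers there stood at 1.76% of their endothelial level in the library labelled control. Endothelial RNA in those droplets was therefore not excluded as the source of the Kupffer value. Loss of Ccn2, the Cre driver and a difference between the animals stay open, untested, as explanations that may act in endothelial cells.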
